A study of Mus musculus with 30 samples.

How the data were processed

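RNA-seq of 8 libraries (ES cells, wild-type motor neurons, and HD and EH motor neurons, 2 each) and ChIP-seq of 22 libraries were grouped from the labels alone. Per the labels, RNA libraries were poly(A)-selected and stranded (TruSeq) and ChIP libraries were made with a ThruPLEX kit. Both knockout lines carry 1 genotype label, Mnx1KO. The antibody list in the labels names an antibody to GFP and none to Mnx1, so how Mnx1 was pulled down is not stated. Per the submitters' processing notes, Trim Galore, Bowtie2, SAMtools, RSEM, STAR, featureCounts, Subread, DESeq2 and MACS2 were used with the mm10 build, with no versions, roles or order.

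The deposited RNA files list 45706 genes by Ensembl ID with an expected count and TPM (transcripts scaled to library size) per gene, the units per the file headers. Symbols were found for 45143 IDs, 563 had none and 56 symbols stood on more than 1 ID. Total expected counts ranged from 11.2 to 53.2 M per library. The authors' peak lists, in MACS2 layout without headers, hold for each peak its start and end in bases, a fold enrichment ratio, a -log10 p and a -log10 q, and for the narrow lists a summit. The authors gave 1 list per mark and genotype, so the libraries of a mark were pooled or merged, in a way not stated, and no spread between ChIP replicates can be had. The lowest -log10 q was 3.01 in the Mnx1 list and 1.10 in the wild-type H3K27ac list. Peak names in the wild-type H3K27ac list read K27ac_KO, while the list's label is wild type, and the label was followed. Of entries with the same start and end, the one of highest enrichment was kept as the region. Entries off the main chromosomes were left out (5943 entries gave 5793 regions for Mnx1).

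Expected counts were rounded and tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in R 4.3.3, with a Benjamini-Hochberg adjusted p of 0.05 as threshold. The 4 comparisons among motor neurons used 1 fit of 6 libraries with a residual of 3 degrees of freedom and a biological coefficient of variation of 0.139. Wild-type motor neurons were compared with ES cells in 1 fit of all 8 libraries (4 degrees of freedom). Each standard error is the fitted log2 fold change divided by the square root of its F statistic. Folds against a group without counts used a floor of 3 counts over the group, and with 1 to 3 counts a ratio with an exact binomial interval. Both cover counting error only, and reads without molecular identifiers are not independent molecules.

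The design, the 27 gene lists, the naming rule and the first set of alternatives were chosen before the data were examined. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, beside an estimated correlation and fry. V3 interneuron genes were too low to be tested among motor neurons, which left 26 lists there. The genes named are Mnx1, the 12 largest rises and 12 largest falls of both lines together, the 10 each way against ES cells, the 5 each way of HD against EH, and up to 4 members of each list with the smallest adjusted p. Some genes that this rule takes are not reported here. Each needed a mean of 1 CPM (5 against ES cells) in the higher group, libraries that did not overlap, and a symbol that is not a provisional name, pseudogene or mitochondrial gene. The genes called in HD, the placental, imprinted and Y-linked genes and those of the fit without EH were named after their values were seen.

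Mnx1 regions were compared with each mark by an overlap of 1 bp or more against 200 random placements on the same chromosome, and with genes by Fisher's exact test with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The gene table used holds no strand and no exons, so either end of a gene stood for its start, and place was end, inside or outside of protein-coding genes. Placements were drawn in Python in place of bedtools, over a span of 2722 Mb set by the highest coordinates among genes and peaks. Coordinates were found for 14813 of 15565 tested genes (95.2%). As a check of the build, 64.0% of wild-type H3K4me3 regions lay within 2 kb of an end of a coding gene, against 17.0% of regions moved by 100 kb. A test of the homeodomain core sequence in Mnx1 peaks was planned and not run, since no genome sequence was used here. Tests of H3K27me3 shares were added after all 5 marks had been looked at; the planned test compared marks in HD only with marks in wild type only.

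The pipeline was tested on simulated data with 200 changed genes. Each gene had the same dispersion in all groups there, so the wider spread of the real EH replicates was not covered. Recovery of 2-fold and 4-fold changes was 73 and 93% in HD, 77 and 98% in EH, 84 and 97% for both lines together, 76 and 98% for HD against EH and 67 and 96% against ES cells, with 6, 30, 14, 15 and 15 false calls. The overlap code found 500 of 500 planted intervals and the same 12 random ones as a direct search. Replicates of each group differed beyond sampling noise, with a chi-square per gene of 44.1 in ES cells, 7.27 in wild type, 63.8 in EH and 5.39 in HD.

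The alternatives were DESeq2 1.42.0 and its size factors, no filter, limma-trend on log2 TPM plus 1 or plus 0.1, the replicate number as a block, a 2-fold minimum, other sets of libraries, each library left out, other distances (5 and 200 kb), a -log10 q of 5, an overlap of 0.5 of each peak and peaks moved by 50 kb. Replicate numbers were not taken as pairs, since the deviations of replicate 1 from its group mean had correlations across genes of -0.167 between wild type and EH, 0.266 between wild type and HD, and -0.248 between EH and HD. Added after the data were seen were fits of each line alone with wild type, EH thinned to 12.9 M counts, gene bodies extended by 50 kb, a match on gene length, and marks or binding at the calls of HD with wild type alone, for marks also at a -log10 q of 5. A leave-one-out fit leaves 1 library in a group, which is assumed to vary like the other groups. Isoforms, reads inside Mnx1 and input libraries were not analysed here.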

Results

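The series holds 30 libraries from mouse embryonic stem (ES) cells and from motor neurons induced from them, 8 by RNA-seq and 22 by ChIP-seq. Its subject is Mnx1 (also called Hb9), a homeodomain transcription factor of motor neurons, and which genes of other neuron types depend on it. RNA was measured in 4 groups of 2 libraries: ES cells, wild-type motor neurons, and motor neurons of HD and EH, the names of 2 lines that the labels give as Mnx1 knockouts. Motor neurons were collected on day 6 of an induction with retinoic acid at 1 µM, the Smoothened agonist SAG at 1 µM, doxycycline at 1 µM and the Notch pathway inhibitor DAPT at 5 µM. The labels explain neither line name and do not say whether replicates were separate cultures, so each error and p-value below covers the spread between these libraries alone. Total expected counts (in M, mega-counts) were 53.2 and 51.3 M in ES cells, 39.8 and 39.7 M in EH, 11.2 and 12.4 M in HD, and 13.9 and 13.9 M in wild-type motor neurons. ChIP-seq covered H3K27ac, H3K27me3, H3K4me1 and H3K4me3 with 2 libraries each in HD and in wild type, H3K9me3 and input with 1 library each, and Mnx1 with 2 wild-type libraries. Values after ± are standard errors of log2 fold changes unless SD is named, and every RNA group has n = 2.

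Mnx1 RNA did not pass edgeR's test against wild type in either line labelled as a knockout. Mnx1 (ENSMUSG00000001566 on chromosome 5, 29473823 to 29478470, mm10) stood at 419 ± 30.9 CPM (counts scaled to library size in M; SD, n = 2) in wild-type motor neurons, 382 ± 42.9 in HD and 599 ± 103 in EH. Its log2 fold change from wild type was -0.14 ± 0.15 in HD and 0.46 ± 0.15 in EH, with edgeR Benjamini-Hochberg adjusted p-values of 0.977 and 0.064. HD lay below EH by a log2 fold change of -0.61 ± 0.15 (edgeR adjusted p = 0.0294). Counts per gene cannot show a change inside the gene, so they do not test the knockouts.

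**Figure D1:**
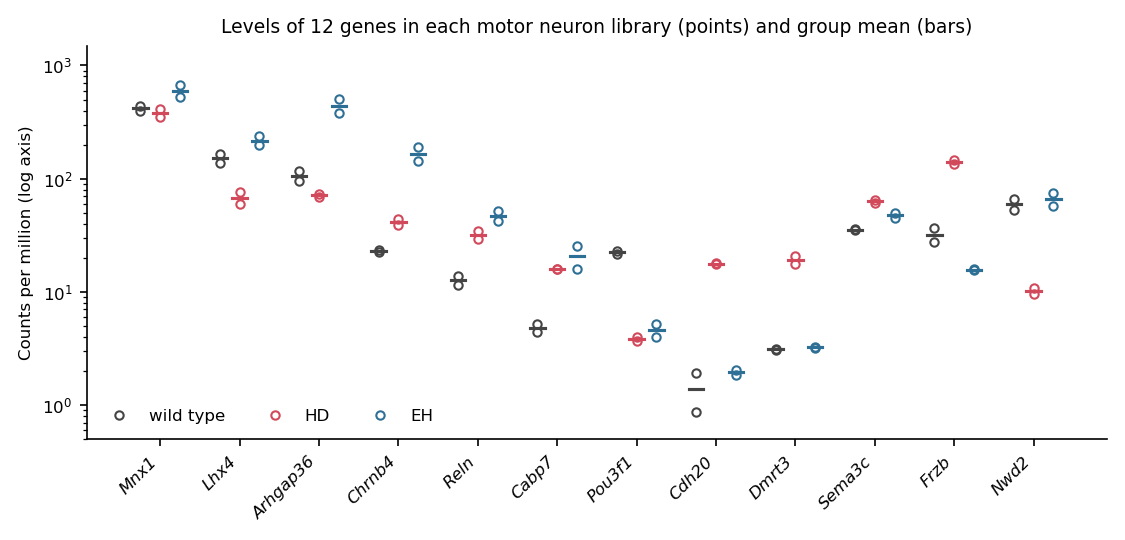
Counts per M library counts (CPM) of 12 named genes in the 6 motor neuron libraries (vertical axis, log scale; horizontal axis, gene; each point is 1 library, coloured by group, and each bar the mean of 2). Mnx1 lies at 419 CPM in wild-type motor neurons, 382 in HD and 599 in EH.

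The comparison of wild-type motor neurons with ES cells shows what the induction changed. Motor neuron genes rose together: the LIM homeodomain gene Lhx3 by a log2 fold change of 9.18 ± 0.16, the acetylcholine-synthesising enzyme Chat by 10.50 ± 0.29, the vesicular acetylcholine transporter Slc18a3 by 9.14 ± 0.24 and Mnx1 by 9.56 ± 0.22 (edgeR Benjamini-Hochberg adjusted p = 9.2e-08 for Mnx1). All 19 measured spinal motor neuron genes rose, as did 19 of 20 pan-neuronal genes, among them Snap25 (8.91 ± 0.17), the neurofilament gene Nefl (6.96 ± 0.15) and the microtubule gene Dcx (13.49 ± 0.38). All 15 anterior and all 11 posterior Hox genes, which mark position along the body axis, rose, with Hoxa5 at 9.53 ± 0.23. All 20 pluripotency genes fell, including Fgf4 (-8.12 ± 0.30), Tdgf1 (-9.01 ± 0.46) and Fbxo15 (-5.48 ± 0.25). All 20 cell cycle genes fell as well, including the replication clamp Pcna (-2.32 ± 0.24) and the kinase Aurka (-2.58 ± 0.29).

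Of 17770 genes tested, 13382 passed the edgeR test at an adjusted p of 0.05, 6898 higher and 6484 lower in motor neurons, and 9629 of them differed at least 2-fold. Among the largest rises were Nyap2 (at least 4100-fold), Asic4 (at least 2790-fold), March4 (at least 2700-fold) and Minar2 (at least 1830-fold), each with no counts in ES cells and set against a floor of 3 counts over the group. Lhx4, a LIM homeodomain gene, had 1 count in ES cells and a ratio of 16800 (counting interval 3020 to 665000). Placental genes were among the largest rises too: Tpbpa (at least 5610-fold), Ctsj (at least 2650-fold), Serpinb9f (at least 2370-fold) and Prl2a1 (at least 1680-fold). Most of these lie in clusters of close copies, so the assignment of their reads is uncertain. The largest falls included the egg coat gene Zp3 (at least 49.7-fold lower), Trh (-9.46 ± 0.36), Platr10 (-9.20 ± 0.42), Nphs1 (-8.57 ± 0.51), Kirrel2 (-8.18 ± 0.41), Spink1 (ratio 359, interval 99.4 to 2970) and the stem cell factor Foxd3 (ratio 250, interval 85.5 to 1210). Nphs1os fell at least 44.4-fold, but it lies antisense to Nphs1 and its reads may belong there.

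The camera test of limma with its preset correlation passed 10 gene lists fixed in advance in this comparison, and 0 did with an estimated one (1 at an unadjusted p under 0.05, and 22 by fry, which does not compare a list with other genes). For 9 of the 10, the value was adjusted p = 0.408 with an estimated correlation, and for the cell cycle list adjusted p = 0.493 with an estimated correlation. Even the pluripotency list, in which every gene fell, did not pass that way. With so few libraries, a list that fails with an estimated correlation is thus not shown to be unchanged. The 10 were the 6 lists above and 4 more that moved mostly upward: axon guidance (27 of 32 rose, 2 fell; Unc5c 7.34 ± 0.19), cadherins and protocadherins (18 of 22 rose, 1 fell; Pcdh7 5.59 ± 0.16), glutamatergic genes (11 of 14 rose; Grin2a 7.27 ± 0.29), and cranial and visceral motor neuron genes (9 of 10 rose, 1 fell; the T-box gene Tbx2 6.13 ± 0.50). The other lists split or did not pass. Motor column genes rose in 7 and fell in 4 of 12, V2a interneuron genes in 2 and 2 of 5, V2b in 5 and 2 of 7, V1 in 5 and 3 of 8, V0 in 4 and 0 of 6, and V3 in 0 and 1 of 2. Dorsal interneuron and sensory genes rose in 6 and fell in 3 of 11, neural progenitor genes in 8 and 6 of 18 (Neurog2 8.72 ± 0.23), GABAergic and glycinergic genes in 8 and 3 of 13, monoaminergic genes in 8 and 2 of 13 (Th 7.27 ± 0.38), and neuropeptide genes in 6 and 4 of 12. Floor plate genes rose in 6 and fell in 2 of 9, glial genes in 6 and 4 of 14 (Nfia 6.89 ± 0.25), neural crest genes in 3 and 1 of 9, endoderm genes in 8 and 3 of 14 (Krt8 4.64 ± 0.29), mesoderm and fibroblast genes in 5 and 6 of 14, and stress and p53 genes in 5 and 10 of 20. Over all lists 321 memberships passed among all genes and 322 adjusted over the list alone. On a scale of TPM plus 1 the split of calls was 9043 higher and 4025 lower, and the median gene stood at 0.43 in place of 0.02, so directions of small changes here are relative to that shift.

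Both knockout lines together were compared with wild-type motor neurons to find genes that moved in the average of the lines. Dbh, the enzyme that makes noradrenaline, rose by a log2 fold change of 2.29 ± 0.31 (edgeR Benjamini-Hochberg adjusted p = 0.0382), and the nicotinic receptor subunits Chrnb4 and Chrna5 rose by 1.81 ± 0.14 and 1.52 ± 0.20. Other rises included the calcium-binding gene Cabp7 (1.89 ± 0.23), Car10 (1.69 ± 0.26), the secreted glycoprotein Reln (1.57 ± 0.15), Lrrn3 (1.48 ± 0.20), Tmtc1 (1.39 ± 0.15), Synpr (1.38 ± 0.20), the interneuron factor Dmrt3 (1.31 ± 0.17) and the Y-linked Eif2s3y (1.25 ± 0.19). Pou3f1, a POU factor of motor columns, fell by -2.44 ± 0.15 (edgeR adjusted p = 0.0079). Fxyd7 (-2.49 ± 0.31), the neurotrophic factor Nrtn (-2.38 ± 0.37), Inpp4b (-2.10 ± 0.32), Ifi44l (-1.94 ± 0.30), Ctsq (-1.76 ± 0.27), C1ql2 (-1.74 ± 0.19), Begain (-1.62 ± 0.17), Rgcc (-1.55 ± 0.18) and Samd9l (-1.51 ± 0.21) fell too. Zxda had no counts in EH, at least 367-fold below wild type, and Hist2h2aa2 likewise, at least 34.3-fold below; both have near-identical copies, so their reads are uncertain.

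In all, 44 genes rose and 83 fell of 15565 tested, 127 in total. Of the list memberships, 10 passed among all genes and 89 adjusted over the list alone, among them Slit3 (1.1 ± 0.16), Pbx3 (0.94 ± 0.14), Lin28b (0.90 ± 0.11), Sst (1.45 ± 0.23) and Cdh22 (-1.07 ± 0.14). An average can rest on 1 line. Sst rose and Cdh22 fell in EH, while HD against EH went the other way by more, so both averages come from EH. Dmrt3 rose by 2.61 in HD fitted with wild type alone, so its average rests mostly on HD. No list passed limma's camera test (0 of 26, 6 at an unadjusted p under 0.05, 1 by fry). The count moved with single libraries: it was 3453 without EH replicate 1, 1317 without EH replicate 2, and 0 by edgeR without HD replicate 1, HD replicate 2, wild-type replicate 1 or wild-type replicate 2, where 1976, 2535, 1834 and 1487 genes had an unadjusted p under 0.05. DESeq2 called 995 genes in all 6 libraries, and edgeR called 5 with the replicate number as a block. Trophoblast marker genes, a list drawn up after the data were seen, were lower in EH and not in HD (22 and 0 of 25 passed), so an average over the lines holds an EH part.

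HD alone differed from wild type in 27 genes by edgeR's test, 21 higher and 6 lower, and in 0 with the replicate number as a block (765 at an unadjusted p under 0.05; DESeq2 without a block called 182). The cadherin Cdh20 rose by a log2 fold change of 3.66 ± 0.32 (edgeR Benjamini-Hochberg adjusted p = 0.0193), and the interneuron factor Dmrt3 by 2.61 ± 0.18. The Wnt antagonist Frzb (2.13 ± 0.14), the adhesion molecule Chl1 (2.01 ± 0.14), the netrin receptor Unc5d (1.74 ± 0.16), the prohormone convertase Pcsk1 (1.92 ± 0.23), Sorcs3 (2.31 ± 0.27), Syt4 (1.75 ± 0.14) and Lypd1 (1.81 ± 0.16) rose as well. Also higher were Lin7a (1.86 ± 0.22), St8sia4 (1.69 ± 0.12), Cttnbp2 (1.55 ± 0.16), Ntng1 (1.31 ± 0.13), Fras1 (1.05 ± 0.10), the nuclear receptor Nr2f1 (1.00 ± 0.12), Ddhd1 (0.96 ± 0.11) and the semaphorin Sema3c (0.83 ± 0.10). Falls were found in 6 genes: Nwd2 (-2.57 ± 0.19), Pou3f1 (-2.54 ± 0.19), Gm9954 (-2.29 ± 0.21), Zfp804a (-1.64 ± 0.15), Arhgap25 (-1.63 ± 0.17) and Lix1 (-1.22 ± 0.15). The pseudogene Dynlt1-ps1 had no counts in wild-type motor neurons and was at least 17.3-fold higher in HD, with uncertain reads.

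None of the 27 calls was left when HD replicate 1, HD replicate 2, wild-type replicate 1 or wild-type replicate 2 was left out (0 by edgeR in each, with 525, 640, 575 and 576 genes at an unadjusted p under 0.05). The spread of the EH libraries entered this test, and a fit of the HD and wild-type libraries without them, chosen after the data were seen, called 336 genes, 259 higher and 77 lower, with all 27 among them. That count was 203 without HD replicate 1 and 533 without HD replicate 2. In it, 3 of 11 GABAergic and glycinergic genes rose and none fell: the GABA-synthesising enzymes Gad2 (2.31 ± 0.33) and Gad1 (1.46 ± 0.28) and the glycine transporter Slc6a5 (2.20 ± 0.44). This list had a limma camera adjusted p = 0.00395 with the preset correlation and adjusted p = 0.433 with an estimated correlation. The prepronociceptin gene Pnoc (3.55 ± 0.46), Sox1 of V2 interneurons and neural progenitors (2.79 ± 0.26) and the vesicular glutamate transporter Slc17a8 (2.40 ± 0.44) rose too. Motor neuron factors Lhx4 (-1.16 ± 0.14) and Isl2 (-0.73 ± 0.13), the column gene Mecom (-1.22 ± 0.09) and the ephrin receptor Epha4 (-1.04 ± 0.09) fell. Other genes of the spinal motor neuron list rose: Cdh7 (1.865 ± 0.358), Onecut1 (1.06 ± 0.11) and Onecut2 (0.65 ± 0.10). The motor column list was split, with 2 of 11 genes higher, Foxp1 (1.05 ± 0.13) and Pbx3 (1.14 ± 0.07), and 2 lower. Of the lists, 9 of 20 cadherins and 6 of 15 anterior Hox genes rose and none fell, 7 of 31 axon guidance genes rose and 1 fell, 3 of 19 spinal motor neuron genes rose and 3 fell, and 4 of 20 cell cycle genes fell.

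Across whole lists in the 6 libraries, neuronal and Hox genes of HD lay above wild type and proliferation genes below. The median log2 fold change was 0.24 in pan-neuronal genes (18 of 20 positive; limma camera adjusted p = 8.1e-09), 0.53 in cadherins, 0.38 in anterior Hox (14 of 15 positive), 0.51 in posterior Hox (11 of 11 positive), 0.31 in GABAergic and glycinergic genes, 0.19 in axon guidance, 0.71 in V1 and 0.13 in glutamatergic genes. For these 8 lists the value was adjusted p = 0.456 with an estimated correlation. Cell cycle genes had a median of -0.36 (0 of 20 positive; camera adjusted p = 0.0018) and pluripotency genes one of -0.45; for both it was adjusted p = 0.622 with an estimated correlation. In total 10 of 26 lists passed limma's camera with the preset correlation and 0 with an estimated one (1 at an unadjusted p under 0.05, and 0 by fry). An estimated correlation passed 0 lists against ES cells too, where every pluripotency gene fell, so it decides little with so few libraries. Few single members passed: 6 memberships among all genes and 55 adjusted over the list alone. Spinal motor neuron genes did not pass as a list (median 0.03, adjusted p = 0.58). None of the 19 passed among all genes by edgeR, and 2 were higher and 5 lower when adjusted over the list alone.

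**Figure D2:**
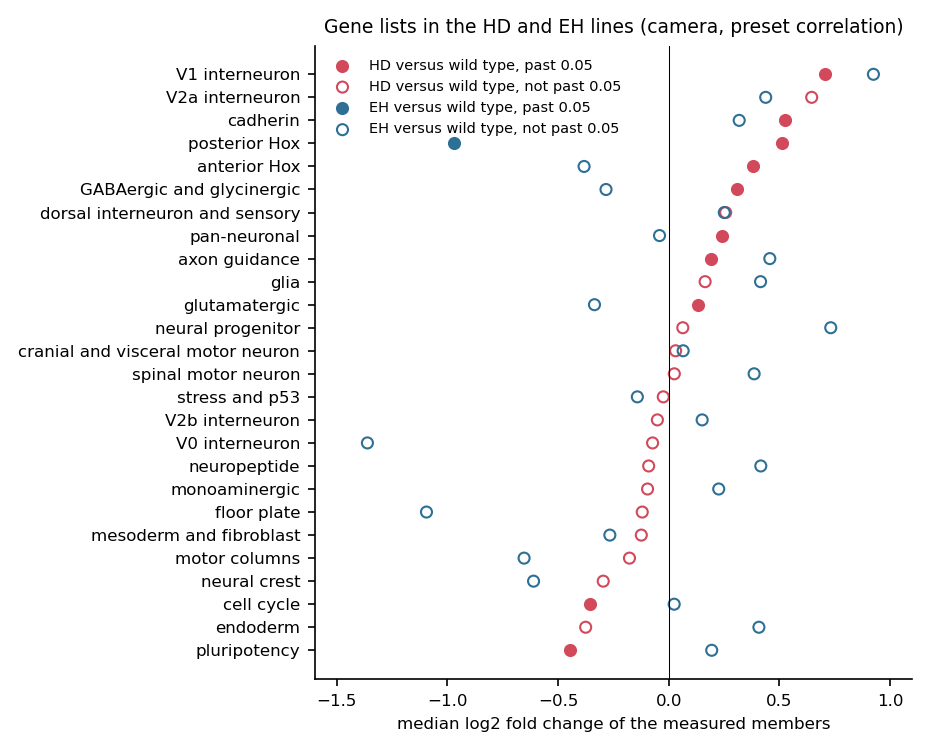
Median log2 fold change of the measured members of each gene list (horizontal axis) in HD and in EH against wild-type motor neurons, 1 line per list; filled points passed limma's camera test at an adjusted p of 0.05 with the preset correlation. Filled points number 10 for HD and 1 for EH, and none passed with an estimated correlation.

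EH differed from wild type far more widely. Noradrenaline genes Dbh and Th rose by log2 fold changes of 3.21 ± 0.31 and 2.25 ± 0.27 and the somatostatin gene Sst by 3.08 ± 0.22 (edgeR Benjamini-Hochberg adjusted p = 0.0025 for Sst). Motor neuron genes rose in 5 of 19 and fell in 0, with Arhgap36 at 2.00 ± 0.16, the guidance ligand Slit3 at 2.00 ± 0.18, the receptor Nrp2 at 1.07 ± 0.14 and the LIM factor Isl1 at 0.89 ± 0.15. Progenitor genes rose in 8 and fell in 1 of 17, with the receptor Notch1 at 1.43 ± 0.12 and Fabp7 at 3.33 ± 0.62. Pou3f1 fell by -2.34 ± 0.18, the retinoic acid enzyme Aldh1a2 by -2.48 ± 0.32, Gad1 by -2.82 ± 0.37 and the interneuron factor Pax2 by -2.31 ± 0.28. Posterior Hox genes fell in 7 of 11 and rose in 0, among them Hoxa6 (-2.83 ± 0.46) and Hoxa7 (-2.06 ± 0.36), and this was the only list past limma's camera (adjusted p = 0.00282), with adjusted p = 0.91 with an estimated correlation.

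Other lists moved in part. Higher and lower members numbered 3 and 4 of 12 for motor columns, 1 and 1 of 5 for V2a, 1 and 2 of 6 for V2b, 2 and 1 of 5 for V1, 0 and 3 of 5 for V0, 4 and 3 of 9 for dorsal interneuron and sensory genes, 2 and 3 of 10 for cranial and visceral motor neurons, and 0 and 0 of 20 for the cell cycle. Glutamatergic genes had 1 and 4 of 12, with the receptors Grin2b at -1.6 ± 0.19 and Grin1 at -1.24 ± 0.15, GABAergic and glycinergic genes 0 and 3 of 13, monoaminergic genes 3 and 2 of 11, neuropeptide genes 2 and 1 of 9, and pan-neuronal genes 2 and 3 of 20, with Snap25 at -0.88 ± 0.11. Axon guidance genes rose in 12 and fell in 7 of 31, cadherins in 3 and 5 of 20, with Cdh22 at -2.37 ± 0.17, and anterior Hox genes in 1 and 5 of 15. Floor plate genes had 0 and 3 of 9, glial genes 1 and 2 of 11, neural crest genes 0 and 2 of 6, endoderm genes 1 and 5 of 14, mesoderm and fibroblast genes 1 and 1 of 10, stress and p53 genes 1 and 2 of 20, and pluripotency genes 2 and 1 of 20. In all 127 memberships passed among all genes and 159 adjusted over the list alone. Lists share some members, such as Pax2 and Lhx1.

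Of 15565 genes, 3301 (21.2%) passed edgeR's test, 1496 higher and 1805 lower in EH, and 1412 of them differed at least 2-fold. A fit of the EH and wild-type libraries alone, chosen after the data were seen, called 2121 genes, 887 higher and 1234 lower. The labels give no batch and no parental clone, so neither can be told apart from EH in these calls. The EH libraries also stood apart in other ways: on the first principal component of the 6 motor neuron libraries, 68.8% of the variance, EH lay at -34.9 and -51.9, HD at 16.9 and 26.1 and wild type at 19.3 and 24.5. Of 25 measured trophoblast markers, 22 were lower in EH and 0 higher, with a median log2 fold change of -1.99, and this stands beside every EH value above. EH replicates differed over 2-fold in 899 genes, against 83 in wild type and 69 in HD. The main fit shared its spread over all motor neuron groups, so its errors may be too small for EH. The count of calls was 152 without wild-type replicate 1, 96 without wild-type replicate 2 and 5925 without EH replicate 1.

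A direct comparison of HD with EH tested whether the lines differed from each other. HD exceeded EH in Gad1 by a log2 fold change of 4.27 ± 0.35 (edgeR Benjamini-Hochberg adjusted p = 0.00215), in the pancreatic and neural factor Mafa by 4.46 ± 0.12, in Cdh22 by 2.61 ± 0.17, in Unc5d by 2.05 ± 0.16 and in Hoxb9 by 2.18 ± 0.27. HD lay below EH in Sst (-3.27 ± 0.23), Arhgap36 (-2.59 ± 0.16) and Lhx4 (-1.63 ± 0.16). At the extremes were Zxda (at least 265-fold higher in HD), Prl5a1 (at least 41.5-fold), Nkx1-1 (ratio 192, interval 51.9 to 1600) and Prl7b1 (4.51 ± 0.49). In the other direction stood Trpc5os (-4.57 ± 0.89), AV320801 (-4.05 ± 0.74), Higd1c (42.2 times higher in EH, interval 7.45 to 1680), Tcf23 (20.9 times, interval 7.05 to 102) and the neurogenic factor Neurod4 (18.0 times, interval 4.87 to 150). Trpc5os lies antisense to Trpc5, so its reads are uncertain. Trophoblast markers were higher in HD in 18 of 25 beside these values.

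In this comparison 3303 genes passed, 1835 higher and 1468 lower in HD. Limma's camera passed 8 of 26 lists with the preset correlation and 0 with an estimated one (0 at an unadjusted p under 0.05; fry 9). Higher in HD were posterior Hox genes (9 of 11 rose), anterior Hox genes (8 of 15), cadherins (9 of 20, 2 fell), pan-neuronal genes (6 of 20, 1 fell), glutamatergic genes (5 of 12, 1 fell), GABAergic and glycinergic genes (4 of 13) and V0 genes (4 of 5). Spinal motor neuron genes were lower in HD, with 10 of 19 falling and 3 rising. For V0, glutamatergic, GABAergic, cadherin and posterior Hox lists the value was adjusted p = 0.644 with an estimated correlation, for anterior Hox adjusted p = 0.709 with an estimated correlation, and for the pan-neuronal and spinal motor neuron lists adjusted p = 0.822 with an estimated correlation. Memberships passing were 147 among all genes and 172 adjusted over the list alone. The gene count was 817 without HD replicate 1, 280 without HD replicate 2, 5209 without EH replicate 1 and 4970 without EH replicate 2.

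By edgeR in the 6 libraries, 6 genes were called in the same direction in both lines. DESeq2 gave 48 shared rises and 15 shared falls (14.2 and 4.39 under independence), and 29 genes called in opposite directions. Each line fitted alone with wild type gave 45 and 15 (13.4 and 6.18), and 25 genes in opposite directions. Fras1 rose by 1.05 ± 0.10 in HD and 0.62 in EH, and Sema3c and Dynlt1-ps1 were among the other shared rises. Pou3f1 fell by -2.54 in HD and -2.34 in EH, and Zfp804a fell in both. Lypd1, Frzb and Nr2f1 rose in HD and fell in EH, with EH log2 fold changes of -0.85, -1.07 and -0.72. The 4 shared rises and 2 shared falls by edgeR in the 6 libraries compare with 2.02 and 0.696 under independence. Both comparisons use the same 2 wild-type libraries, too few to be divided, so part of that excess may come from the shared controls. The size of that part was not measured. In 20 simulations of unchanged groups with those controls, 0.15 shared rises were found on average. Unchanged groups give few calls in either line, so this cannot size it where EH had 3301 calls. Across 14511 genes, which are not independent replicates, the fold changes of the lines had r = 0.241 and a covariance of 0.0600, against 0.511 and 0.0372 in the simulations.

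**Figure D3:**
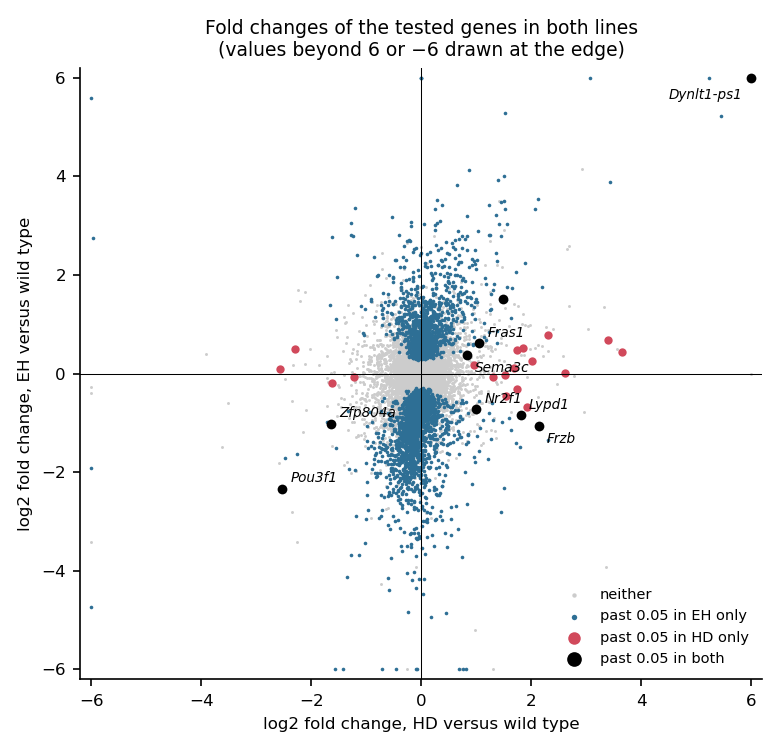
Log2 fold change against wild-type motor neurons in HD (horizontal axis) and in EH (vertical axis), with 1 point per tested gene, coloured by which of the edgeR tests it passed. Pou3f1 lies at -2.54 and -2.34 and Fras1 at 1.05 and 0.62, while Frzb lies at 2.13 and -1.07.

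Mnx1 binding was mapped in wild-type motor neurons to 5793 regions of median length 527 bp. The labels name no antibody to Mnx1, and the series has no Mnx1 ChIP in a knockout line. Whether each region is specific to Mnx1 was therefore not tested. The strongest lay on chromosome 2 from 91649602 to 91650483 (20.1-fold enrichment), 0.033 kb from an end of Zfp408. The next were at chromosome 4, 130834061 to 130834804 (13.7-fold), 8.12 kb from the syndecan gene Sdc3; chromosome 4, 124477819 to 124478539 (13.7-fold), 179 kb from Pou3f1; chromosome 17, 62882469 to 62883664 (12.4-fold), 1.88 kb from the ephrin gene Efna5; and chromosome 5, 29620190 to 29621106 (12.3-fold), inside a gene and 51.4 kb from an end of Ube3c. Within 50 kb of an end of Mnx1 itself lay 7 regions, the strongest at 29484933 to 29486356 on chromosome 5 (5.96-fold). Near named genes, a region at chromosome 2, 27183640 to 27184330 (9.94-fold) lay 0.735 kb from an end of Dbh, one at chromosome 9, 55067263 to 55068030 (8.55-fold) 18.7 kb from Chrnb4, and one at chromosome 6, 52204155 to 52204992 (10.6-fold) at an end of Hoxa6. No region lay within 50 kb of an end of Cdh20, Cabp7, Chrna5, Pou3f1, Sst, Gad1, Gad2, Isl1 or Lypd1.

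Mnx1 regions carried marks of active promoters and enhancers. In wild type, 77.3% overlapped H3K27ac (95% Wilson interval 76.2 to 78.3%), 61.8% H3K4me1 (60.6 to 63.1%) and 55.7% H3K4me3 (54.4 to 57.0%), against 1.58, 8.42 and 2.26% of random placements. H3K27me3, a mark of Polycomb repression, covered 3.33% (random 1.1%), and the heterochromatin mark H3K9me3 0.276% (random 1.31%), 16 regions. Each ratio lay beyond all 200 placements (permutation p = 0.01, two-sided, the smallest they can give). The ratios to random were 48.8 for H3K27ac, 7.34 for H3K4me1, 24.7 for H3K4me3 and 3.02 for H3K27me3, and against the same regions moved by 50 kb in place of random placements they were 21.0, 3.89, 12.4 and 1.66. H3K27ac without H3K4me3, a pattern of distal enhancers, was found at 25.9% of the regions, H3K4me1 without either at 15.5%, and none of the 5 marks at 2.87%. By place, 40.5% of summits lay within 1 kb of an end of a protein-coding gene (random 3.2%), 30.7% inside one (random 39.6%) and 28.8% outside (random 57.2%). Peak names in the wild-type H3K27ac list read K27ac_KO, against its label, so each H3K27ac value here rests on the label.

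**Figure D4:**
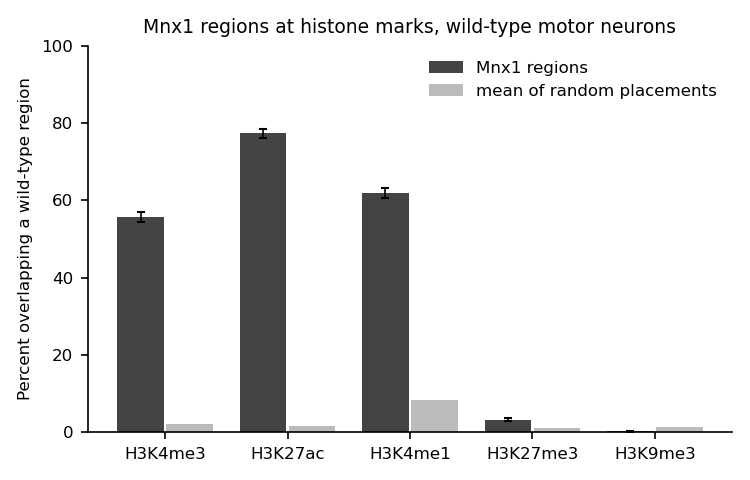
Percent of the 5793 Mnx1 regions that overlapped a wild-type peak of each histone mark (vertical axis; bars start at 0), with 95% Wilson intervals, beside the mean of 200 random placements. H3K27ac overlapped 77.3% against 1.58% at random, under the label of a list whose peak names read K27ac_KO.

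Genes that changed in the knockout lines were then asked for nearby Mnx1 binding. A Mnx1 region lay within 50 kb of an end of 17 of 43 genes higher in both lines together (39.5%; Dbh and Chrnb4 among them) and of 28 of 77 lower genes (36.4%), against 48.3% of other tested genes. The odds ratios were 0.699 and 0.611 (2-sided Fisher exact p = 0.286 and 0.0395, Benjamini-Hochberg adjusted 0.429 and 0.118 over 6 tests). In HD it was 9 of 21 higher genes, including Dmrt3 and Frzb, and 3 of 5 lower ones, with odds ratios of 0.805 and 1.61 (Fisher exact, adjusted p = 0.677 for both). In EH, 733 of 1458 higher genes (50.3%, odds ratio 1.07, Fisher adjusted p = 0.429) and 766 of 1753 lower genes (43.7%, odds ratio 0.818, Fisher adjusted p = 0.000642) had one, against 48.7% of other genes. None of the 6 tests showed more binding within 50 kb of changed genes, and genes lower in EH had it less often. For these the odds ratio was 0.675 within 5 kb (317 of 1753 genes, 18.1% against 24.7%; Fisher exact p = 7.73e-10, not adjusted) and 0.961 within 200 kb, and the 22 of 25 trophoblast markers lower in EH stand beside it. Within 5 kb the odds ratio was 0.326 for the higher genes of both lines together and 0.160 for those of HD (4 of 43 and 1 of 21 genes; Fisher exact p = 0.0295 and 0.0396, not adjusted). Other settings gave odds ratios nearer 1 for higher genes: 1.09 for both lines with DESeq2 calls (191 of 368 genes, Fisher exact p = 0.428, not adjusted), and for HD 1.12 with the gene body extended by 50 kb and 0.944 within 50 kb for the calls of HD and wild type alone (119 of 252 genes, Fisher exact p = 0.657, not adjusted). For the lower genes of both lines together it was 0.475 within 5 kb (Fisher exact p = 0.0226, not adjusted), and for those called by DESeq2 it was 0.647 within 50 kb, 233 of 597 genes (Fisher exact p = 3e-07, not adjusted). The tests of each line alone were added after the data were seen.

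Histone marks were compared between HD and wild type as lists of peaks, without a test, because the libraries of a mark were combined into 1 list. H3K27me3 had 9365 regions (20.3 Mb, median enrichment 3.49-fold) in wild type and 5729 (12.9 Mb, 3.39-fold) in HD; 51.0% of the wild-type regions were found in HD and 96.1% of the HD regions in wild type. H3K4me3 was shared at 88.2% of 21286 wild-type and 98.6% of 19226 HD regions. H3K27ac had 19174 regions in the list labelled wild type (peak names K27ac_KO) and 20698 in HD, with 87.2 and 80.0% shared. At a -log10 q of 5 or more the wild-type shares were 88.5% for H3K4me3 and 93.3% for H3K27ac. H3K4me1 went from 110851 to 90369 regions (68.4 and 89.6% shared) and H3K9me3 from 21120 to 15427 (44.9 and 63.3%). At Mnx1 itself H3K27me3 was listed in wild type only. The lists differ in their highest enrichment, 119-fold against 50.8-fold for H3K4me3, so part of these differences can follow how much was called.

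Changes of H3K27ac at the changed HD genes were then counted. Of the genes higher in HD, 6 of 21 had an H3K27ac peak within 2 kb of an end in HD only and 0 in wild type only, including Dmrt3 and Frzb. Of those lower, 0 of 5 had one in HD only and 2 in wild type only, including Nwd2. The 2-sided Fisher exact test gave p = 0.0357, adjusted p = 0.179 over 5 marks, and the other 4 marks had an adjusted p of 1. With the calls of the HD and wild-type libraries alone, chosen after the data were seen, the counts were 25 and 2 of 252 higher genes and 0 and 7 of 70 lower genes (Fisher exact adjusted p = 3.34e-05), while other genes had 388 in HD only and 166 in wild type only. Higher genes against other genes gave a Fisher exact adjusted p = 0.0438 for these calls and 0.93 for the 21. At a -log10 q of 5 or more the counts were 29 and 1 of 252 higher genes and 2 and 3 of 70 lower genes (Fisher exact adjusted p = 0.0292, and 0.232 for higher against other genes). The wild-type side of each of these counts comes from the list whose peak names read K27ac_KO.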

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

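The direct comparison of the lines was planned, and the tests that weigh explanations below were chosen after the result was seen. A test of the difference between HD and EH passed for 3303 genes. Of the 9 genes called in both lines against wild type, 7 differed between the lines by edgeR's direct test, given here as HD against EH log2 fold changes. Lypd1 (2.66), Frzb (3.2) and Nr2f1 (1.72) rose in HD and fell in EH. Sema3c (0.47) and Fras1 (0.43) rose in both and more in HD, Zfp804a (-0.63) fell in both and more in HD, and Dynlt1-ps1 (-1.98) rose in both and more in EH. Mnx1 itself differed by -0.61.

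The EH libraries lay apart from HD and wild type, at -34.9 and -51.9 on the first principal component. Greater depth is argued against, since EH thinned to 12.9 M counts still gave 3166 calls. More RNA of undifferentiated ES cells is argued against too, from levels in ES cells. That test covers ES cells only, not neural progenitors, whose genes rose more often than they fell in EH. The 5 pluripotency genes of at least 500 CPM in ES cells stood in EH at 0.19 to 3.21% of that level, and a share of 3.21% of ES cell RNA could give the change of 2 of the 3301 genes called. Pluripotency genes were called higher in EH in 2 of 20 and lower in 1 against wild type, and higher in 6 and lower in 1 against HD (median log2 fold change of HD against EH -1.002). Fewer trophoblast-like cells may account for part of the genes lower in EH: 22 of 25 measured markers fell and none rose, with a median log2 fold change of -1.99. Tpbpa stood at 151 CPM in wild type, 12.2 in EH and 159 in HD, and Peg10 at 3347, 2066 and 3301. The EH value of Tpbpa is the mean of 21.6 and 2.88 CPM, so its fold depends on the library. For the genes higher in EH the 482 rises of at least 2-fold argue against that explanation. A difference between the lines themselves stays open and untested. The labels do not say whether the groups were induced and sequenced together or whether the lines share a parental ES clone, so a batch or a clone of origin cannot be told apart from EH in any of the 3301 calls. EH also had 39.8 and 39.7 M counts against 11.2 to 13.9 M in the other motor neuron libraries, and all 4 Y-linked genes were higher in it. The labels name no sort that would remove such cells.

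Neuronal genes lay higher in HD, with a pan-neuronal median log2 fold change of 0.24. The values below argue against scaling between libraries only with genes taken as independent. Fewer cycling cells cannot be told apart from other explanations here. Scaling would move genes of the same expression alike. The list lay above 20 genes drawn from the same deciles of expression by a difference in medians of 0.23 (2-sided permutation p = 2e-05 with genes drawn as independent). Drawn genes had a median of 0.01 (highest draw 0.16), and all tested genes one of -0.014. With DESeq2 size factors the medians were 0.24 for pan-neuronal and -0.35 for cell cycle genes. A factor common to all genes of a library gives no such split. With genes taken as independent, this argues against scaling for this list. With the estimated correlation of its members, 0.761, limma's camera gave an unadjusted p = 0.179 for the list (adjusted p = 0.456). The criterion for setting scaling aside asked for a p under 0.05 both ways, and this one was above it. Whether the list rose beyond the joint spread of its members therefore stays open, and scaling was not decided by that criterion. Fewer cycling cells could raise neuronal genes, and 0 of 20 cell cycle genes had a positive fold change, which goes with it. The spinal motor neuron list lay below the pan-neuronal one by a difference in medians of -0.21, but its members went both ways with an SD of 0.70 (10 of 19 positive), so this decides nothing. The state of Mnx1 stays open and was not tested, since 1 line cannot separate it from other features of that line.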

How the results depend on the processing

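Fits of a line alone with wild type, HD fits without an EH library, thinning of EH, gene bodies, a match on gene length, and tests of each line's own calls, also at a -log10 q of 5, were added after the data were seen. No named gene reversed a call in these settings. Calls of named genes held in 323 settings and ended in 163 for 27 genes of HD, 798 and 202 for 77 of EH, 248 and 186 for 31 of both lines, 873 and 139 for 92 of HD against EH, and 1270 and 6 for 116 against ES cells. Named genes without a call gained one in 266, 26, 198, 24 and 0 settings, with the same direction. Wild-type motor neurons against ES cells kept a count within 1.5 times of 13382 in each setting.

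The HD count of 27 was 182 with DESeq2, 142 without a filter, 0 with the replicate block (765 at an unadjusted p under 0.05), 0 to 0 without a library, 323 and 323 without EH replicate 1 or 2, and 336 from HD and wild type alone, which became 203, 533, 266 and 311 without HD replicates 1 and 2 and wild-type replicates 1 and 2. The count of 127 for both lines was 80 with a 2-fold minimum, 995 with DESeq2, 953 without a filter, 5 with the block, 78 with all 8 libraries, 264 with EH thinned, and 0 to 3453 without a library. The EH count of 3301 was 1412 with a 2-fold minimum, 2080 with the block, 2121 with EH and wild type alone and 96 to 5925 without a library. The HD against EH count of 3303 was 1419, 2154 and 280 to 5209 under the 2-fold minimum, the block and leaving out a library. A fold minimum removes calls by construction. For HD, the count of 336 from HD and wild type alone, with all 27 calls kept, goes with the spread of EH in the shared fit. In the other settings the cause was not tested. Shared calls of 6 became 63 with DESeq2 and 60 with each line alone.

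With an estimated correlation 0 lists passed camera in HD, EH, HD against EH and motor neurons against ES cells. With the block 1 list passed for both lines. Members adjusted over the list alone numbered 89 for both lines and 55 for HD.

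Set against the same regions moved by 50 kb in place of random placements, Mnx1 regions gave ratios of 21.0 for H3K27ac, 1.66 for H3K27me3, 3.89 for H3K4me1 and 12.4 for H3K4me3, and a -log10 q of 5 gave 0.341 for H3K9me3. Odds ratios of binding near genes of both lines were 0.326 (5 kb), 1.09 (DESeq2 calls) and 1.06 (gene body) for higher genes, and 0.475 (5 kb), 0.647 (DESeq2 calls), 0.715 (200 kb), 0.624 (-log10 q of 5), 0.648 (gene body), 0.637 (matched on expression) and 0.632 (and on length) for lower genes. For HD they were 0.160 (5 kb) and 1.12 (gene body) for higher and 0.798 (5 kb) for lower genes, and for EH 0.969 (5 kb) and 0.955 (200 kb) for higher and 0.675 (5 kb) and 0.961 (200 kb) for lower genes. The cause was not tested. Wild-type regions shared with HD, at a -log10 q of 5 and at an overlap of 0.5 of both peaks, were 93.3 and 76.9% for H3K27ac (peak names K27ac_KO), 65.4 and 36.5% for H3K27me3, 67.0 and 53.4% for H3K4me1 and 35.0 and 28% for H3K9me3, and 88.5 and 86.2% for H3K4me3. H3K27ac at the calls of HD and wild type alone had an adjusted p of 3.34e-05, and 0.0292 at a -log10 q of 5, from more genes. The homeodomain core test and its alternatives were not run. Depth limits genes of low count most in HD, at 11.2 and 12.4 M.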

Other observations

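The lists of trophoblast, imprinted and Y-linked genes and the H3K27me3 tests were chosen after results were seen: all trophoblast and Y-linked values and 5 imprinted ones, and the H3K27me3 shares but not those of matched genes. Imprinted genes, expressed from 1 parental copy, split in EH: 7 of 21 were higher than in wild type and 6 lower, against 0 in HD by edgeR in the 6 libraries and 1 in HD and wild type alone (Dlk1, -0.91 ± 0.14). The 22 of 25 trophoblast markers lower in EH (median -1.99) stand beside these falls, and Peg10 is in both lists. The noncoding RNAs Rian (log2 fold change 3.51 ± 0.81) and Peg13 (3.82 ± 0.60) and the H19 RNA (1.45 ± 0.20) were higher, and the growth factor Igf2 (-3.59 ± 0.92) and the cell cycle inhibitor Cdkn1c (-2.99 ± 0.65) were lower. Rian also differed between replicates, at 330 and 87.2 CPM in wild type. All 4 Y-linked genes were higher in EH, with a median of 2.11 and Ddx3y at 1.61 ± 0.13, and none passed in HD.

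H3K27ac regions of the list labelled wild type (peak names K27ac_KO) were found again in HD for 96.3% of the 4412 at Mnx1 peaks, 84.4% of those elsewhere and 93.1% of those elsewhere with matched enrichment. The same shares were 97.6, 86.6 and 96.9% for H3K4me3 and 92.4, 67.5 and 86.5% for H3K4me1. From HD to wild type they were 93.7, 76.1 and 90.0% for H3K27ac. The pattern was thus particular neither to H3K27ac nor to that direction.

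Genes higher in HD often carried H3K27me3 in wild type: 14 of the 21 calls (66.7%), against 25.4% of other genes, and 160 of the 252 calls with coordinates from HD and wild type alone (63.5%), against 24.5%. At a -log10 q of 5 or more these became 6 of 21 (28.6%) against 16.1%, which did not pass (Fisher exact adjusted p = 0.338, against 0.000419 for all peaks), and 109 of 252 (43.3%) against 15.4%. Low expression may add to this. Genes matched on mean level over the motor neuron groups, not in wild type alone, carried it in 20.9% of cases (highest draw 31.3%). This argues against that mean level as the cause. Promoters with H3K4me3 could add to it as well, but genes also matched on that mark had it in 21.4% (highest draw 31.7%). At a -log10 q of 5 or more the matched shares of the 252 were 12.4 and 12.7% (highest draws 19.8 and 20.6%). Each gave a 2-sided permutation p = 0.0002, the smallest that 10000 draws can give. Lower genes also carried it more often than matched genes (35 of 70 against 20.6 and 18.4%), so the mark was not particular to rises, and a role of Mnx1 was not tested.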
